A study of Mus musculus with 12 samples.

How the data were processed

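Total RNA from plucked skin of 12 male mice was measured on 12 one-colour expression arrays, 1 array per mouse. Per the labels, the mice had a mixed C57Bl6/129Sv background, were wild type (WT) or carried a conditional knockout of Sox4 in skin (cKO), and were sampled 12 days after plucking. Per the labels, RNA was extracted with Trizol, purified with a QIAGEN kit, amplified with T7 polymerase and labelled with Cy3-CTP. The mice came from experiments named Exp 1 (68 to 72 weeks old) and Exp 2 (16 to 20 weeks old), with 3 mice of each genotype in each.

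The scanner files hold spot values of Feature Extraction 11.5.1.1. Per the file headers, gProcessedSignal is a background-subtracted intensity, not scaled between arrays, and gMedianSignal and gBGMedianSignal are raw spot and local background intensities. The files also hold 0 or 1 flags of the software, per the file headers, for spots well above background, saturated spots and outlier spots. The value table deposited by the authors holds log2 values whose columns share almost the same distribution. The submitters' processing notes name limma. The background correction and normalization steps are not given in the sources used here. All 12 columns of that table were matched to samples. The table served as an alternative only, because the column of cKO mouse 1 differed from the array of that mouse.

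Spots marked as outliers were left out, the log2 processed signal was averaged over the spots of a probe, and the 75th percentile of each array was subtracted. A probe with every spot marked was treated as missing, which left 25 missing values. Probes were named by matching their transcript accession to the RefSeq gene table of GRCm38. Of 55681 probes, 27509 had a symbol. The 28172 without one were left out of the gene fits, and entered, where kept, only the alternative that tested every probe. A probe was kept when it was well above background on at least 3 of the 12 arrays. For each gene the kept probe with the highest mean signal was used, which gave 16183 genes, 4130 of them with several kept probes. Probes of near-identical genes, such as the Mup and Krtap families, can read each other's transcripts. Array coordinates were not used.

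The genes were fitted in R 4.3.3 with limma 3.58.1 as 4 group means (8 residual and 2.3 prior degrees of freedom, empirical Bayes without trend). There were 6 contrasts: cKO minus WT averaged over both experiments, the same difference in Exp 1 and in Exp 2, the difference between these differences (interaction), and Exp 1 minus Exp 2 within WT and within cKO. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, at a threshold of 0.05. Errors beside group means are SD and errors beside differences are SE. The number of arrays limits the precision. Where a gene was not well above background on any array of a group, the fold is given as a bound ("at least"), computed after raising lower values to the lowest signal that passed as above background on the same array, beside the fitted difference, which is then not a reliable size.

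The comparisons, the alternatives, the rule for naming genes and 30 gene lists were chosen before the data were examined. The lists were hair shaft keratins, keratin-associated proteins, inner root sheath, hair matrix and shaft regulators, hair follicle stem cell and bulge, dermal papilla, Wnt pathway targets, hair cycle arrest signals, DNA replication (S phase), mitosis, melanocyte, interfollicular differentiation, basal keratinocyte, companion layer and stress keratinocyte, sebaceous gland, adipocyte, skeletal muscle, fibroblast and collagen matrix, endothelial, macrophage, lymphocyte, mast cell, Langerhans cell, peripheral nerve, red blood cell, interferon response, immediate early and heat shock, p53 targets, cell cycle inhibitors and senescence, and SoxC family with reported Sox4 targets. Each list was tested against all other genes with camera of limma, at a preset correlation between genes of 0.01 and with an estimated correlation, on genes without missing values, and adjusted over the lists of a contrast. A list shift is the median log2 difference of its members. An exact permutation test of each list's mean per mouse, with labels exchanged within experiments, was added after the data were seen.

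Genes named were Sox4, the 10 largest differences each way among genes past the threshold for the averaged genotype contrast and the contrasts between experiments, the 5 largest each way for the other contrasts (by smallest p where none passed), and up to 4 members of a list by smallest p. Identifier-only names were left out, except where a count of 5 or fewer needed them. A further gene that the rule names is not reported here. Other called genes given below were chosen after their values were seen.

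Slide, read from the array names, was the known batch: slide 1 held 6 arrays (WT 2, 3 and 5, cKO 1, 2 and 6), slide 2 held 5 (WT 1, 4 and 6, cKO 4 and 5) and slide 3 held 1 (cKO 3). All arrays were scanned on 1 day on 1 scanner. Contrasts were refitted with slide as a block and within slides 1 and 2. Within a slide a group was often 1 array. The spread in the fits by group then came from the pairs WT 2 and 3 and cKO 2 and 6 within slide 1 (2 residual degrees of freedom) and from the pair WT 4 and 6 within slide 2 (1). A P1 or P2 tag in the array names, whose meaning is not given in the sources used here, coincided with genotype in Exp 2. Alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization, median scaling, the authors' table, other filters and probe choices, trend and robust variance, array weights (which stopped before reaching their tolerance), slide, tag, age or mouse number as terms, single-experiment fits and each mouse left out. The planned normexp input was the mean spot signal, which the files used here do not hold, so the median spot signal was used. Alternatives added after the data were seen were a skeletal muscle covariate, WT mouse 5 and cKO mouse 5 left out together, the authors' table without cKO mouse 1, and fits by group within slides. In fits that are not orthogonal the errors of genes with missing values are approximate. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, and files were read with the R packages data.table (version 1.17.8) and jsonlite (version 2.0.0).

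The procedure was tested on simulated data drawn independently per gene, with each gene's own mean and spread, and with known differences added to 200 of 16158 genes. A difference of 1 on the log2 scale was recovered in 74% of genes for the averaged genotype contrast and in 33% for the interaction. A difference of 2 was recovered in 93% and 80%. Of the calls, 3.47% and 4.24% were false. For the genotype contrasts in Exp 1 and Exp 2, a difference of 1 was recovered in 55% and 50% of genes. There 5.84% and 5.88% of the calls were false. For Exp 1 against Exp 2 the false share was 1.41% in WT and 4.76% in cKO.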

Results

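Gene expression was measured in plucked skin of 12 male mice, 12 days after plucking, to ask what Sox4 contributes to the regrowth of hair and to the activation of follicle stem cells. Sox4 encodes a transcription factor of the SoxC family. WT and cKO skin were each sampled from 3 mice in Exp 1 (68 to 72 weeks old) and 3 mice in Exp 2 (16 to 20 weeks old), so age and experiment cannot be told apart. Between 53.9% and 62.6% of probes were well above background on each array, and the 75th percentile of the processed signal lay between 364 and 554 intensity units, with cKO mouse 5 lowest in both measures. Correlations between arrays across genes ranged from 0.964 to 0.992 within groups and from 0.939 to 0.992 between groups (genes are not independent replicates). The first principal component held 46.9% of the variance and the second 17.2%, on which cKO mouse 5 lay at -73.6. All values below are log2 signal relative to the 75th percentile of the array.

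The level of Sox4 was compared first, because it is the targeted gene. Sox4 was 2.13 ± 0.18 in WT skin and -3.40 ± 0.69 in cKO skin (SD, n = 6 and 6 mice), a log2 difference of -5.54 (SE 0.12, adjusted p = 3.8e-09 in limma), or 46.4-fold lower. The lowest WT mouse was at 1.90 and the highest cKO mouse at -2.55. In WT mice 1 to 6 the level was 1.90, 2.20, 1.97, 2.16, 2.43 and 2.15, and in cKO mice 1 to 6 it was -3.05, -3.86, -2.55, -2.82, -3.88 and -4.26. An exact permutation test with labels exchanged within experiments gave p = 0.005 (two-sided), the smallest that its 400 arrangements can give. This probe was above background in 6 of 6 WT and 4 of 6 cKO mice, the 4 being 1 of 3 in Exp 1 and 3 of 3 in Exp 2. A second Sox4 probe read -0.37 ± 0.26 in WT and was not above background in any cKO mouse, which is at least 23.2-fold lower. The difference was -6.02 in Exp 1 (SE 0.17, adjusted p = 5.5e-08) and -5.05 in Exp 2 (adjusted p = 3.3e-07), with the interaction not past the threshold (-0.97, adjusted p = 1). Within slide 2 alone the difference was -5.32 and did not pass (adjusted p = 0.184). Where the deleted part of the gene lies relative to the probes is not given in the sources used here.

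**Figure D1:**
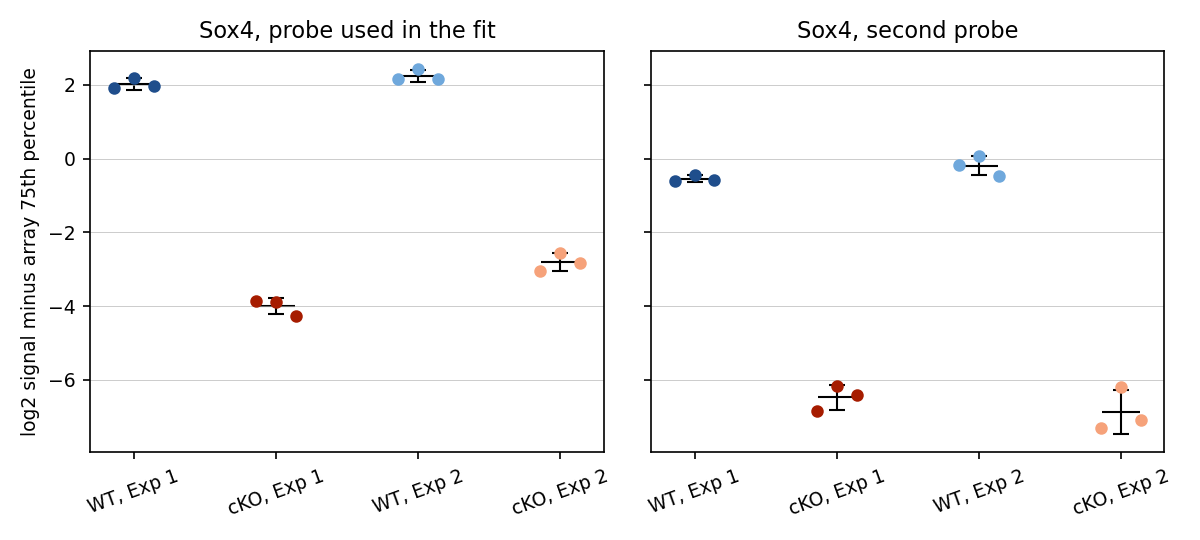
Sox4 signal (log2, relative to the 75th percentile of the array) for each mouse (points) with group mean and SD, for both Sox4 probes, in WT and cKO skin of Exp 1 and Exp 2. With the probe used in the fit every WT mouse lies at 1.90 or above and every cKO mouse at -2.55 or below.

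Averaged over both experiments, cKO skin was compared with WT skin to ask which genes differ when Sox4 is deleted. Mex3a, which encodes an RNA-binding protein, fell from 0.64 ± 0.24 in WT to -1.98 ± 0.16 in cKO (SD, n = 6 and 6), a difference of -2.63 (SE 0.11, adjusted p = 1.2e-06). Tead2, a DNA-binding partner of the Hippo pathway and a reported Sox4 target, fell from 1.15 ± 0.12 to -0.08 ± 0.18, a difference of -1.23 (SE 0.092, adjusted p = 0.00032). Grp, which encodes a signalling peptide, fell by 2.23 (SE 0.20, adjusted p = 0.0012), and Plppr3 fell by 2.30 (SE 0.17, adjusted p = 0.00032), although a second Plppr3 probe had the opposite sign. The other large decreases were in Klk15 (-3.28 ± 0.54, adjusted p = 0.033), Slc5a7 (-3.16 ± 0.46, adjusted p = 0.017), Spink12 (-2.60 ± 0.34, adjusted p = 0.010), Atp1a4 (-2.32 ± 0.30, adjusted p = 0.010), B4galnt4 (-2.13 ± 0.27, adjusted p = 0.0078) and Zfp184 (-2.11 ± 0.37, adjusted p = 0.047). Klk15, Slc5a7, Spink12 and B4galnt4 were not above background in any cKO mouse and were at least 5.49-fold, 3.64-fold, 1.95-fold and 2.04-fold lower. Only 5 genes were higher in cKO: Fam151a (1.02 ± 0.18, adjusted p = 0.043, at least 1.02-fold), Timd4 (adjusted p = 0.043; not above background in any WT mouse, with a bound of 1-fold, so no size is given), Cd163l1 (0.95 ± 0.14, adjusted p = 0.017), Eml5 (0.80 ± 0.13, adjusted p = 0.032) and Pcdh20 (0.58 ± 0.10, adjusted p = 0.047). The last 2 rested on Exp 1, with 1.44 there and 0.15 in Exp 2 for Eml5, and 1.15 and 0.0011 for Pcdh20. Timd4 rested on Exp 2, and Fam151a was not above background in any mouse of Exp 1. Refitted under the alternatives, Mex3a kept its direction and call in 31 of 32 fits and Tead2 in 29 of 32. Pcdh20 kept them in 5 of 32, Eml5, Fam151a and Timd4 in 6 of 31 each, and Klk15 and Zfp184 in 12 of 31 each.

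Of 16183 genes, limma called 68 for this contrast, 5 higher and 63 lower in cKO, with 1967 at an unadjusted p under 0.05. In 62 of the 68 the difference had the same direction at an unadjusted p under 0.05 in both experiments. In Gm773, 4930550L24Rik, Spaca9, Eml5 and Pcdh20 it did so in Exp 1 only and in Timd4 in Exp 2 only (Gm773, 4930550L24Rik and Spaca9 were named after their values were seen). The 68 were chosen on the mean of the differences in both experiments, so this agreement is partly built in and is not a replication. Of all 68 called genes, 15 had other kept probes, and 16 of these 18 probes had the same sign as the probe used. Among the lower genes were the cytoskeletal genes Evl (-1.45), Marcksl1 (-1.08), Tmsb10 (-0.71) and Stmn1 (-0.70), the cell cycle kinase gene Cdk4 (-0.62) and the Wnt target Sp5 (-0.96 ± 0.16, adjusted p = 0.033). The count was 55 with slide as a block (4 higher, 51 lower), 5 within slide 1 (2075 at an unadjusted p under 0.05) and 0 within slide 2 (997), where 6 and 5 arrays were left. It was 11 with the skeletal muscle list mean as a covariate, 31 with the array-name tag as a term and 16 in the authors' value table (36 without its column of cKO mouse 1). Leaving out 1 mouse moved it to 31 (WT 3), 34 (WT 4), 35 (WT 5), 39 (cKO 1), 41 (cKO 4), 42 (cKO 3), 43 (WT 2), 106 (cKO 5) or 122 (cKO 6). Median scaling moved the median of all genes to -0.12 and called 51 genes, all lower.

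Cell division genes were lower in cKO skin as groups at the preset correlation, but not with an estimated one or per mouse after adjustment. Single mice of the genotypes overlapped in the mean level of both lists below. Of 24 mitosis genes, among them Tpx2 (-0.54 ± 0.10, adjusted p = 0.057) and Top2a (-0.44 ± 0.11, adjusted p = 0.13), 24 had a negative difference, with a median of -0.35 (camera adjusted p = 9.8e-10 at the preset correlation, adjusted p = 0.54 with an estimated correlation). Of 25 DNA replication genes, including Mcm7 (-0.59 ± 0.11, adjusted p = 0.057), 24 were negative, with a median of -0.34 (7.2e-09 preset, adjusted p = 0.54 with an estimated correlation). No member of either list passed over all genes, while 12 mitosis and 5 replication genes passed adjusted over the list alone. The mitosis median was -0.37 with slide as a block, -0.52 within slide 1 and -0.23 within slide 2, and the replication median was -0.33, -0.45 and -0.19. The exact permutation p of the mean per mouse was 0.02 for mitosis and 0.015 for replication before adjustment, and no list passed after it (smallest 0.12). With the muscle covariate the medians were -0.23 and -0.24.

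The dermal papilla list, genes of the mesenchymal cluster that instructs the follicle, had a median of -0.38 with 13 of 15 genes negative (Wif1 -0.90 ± 0.29, Alpl -0.49 ± 0.12; preset adjusted p = 0.0045, adjusted p = 0.54 with an estimated correlation). Its median was -0.40 with slide as a block, -0.55 within slide 1 and -0.39 within slide 2, and 1 member passed adjusted over the list alone. The melanocyte list, genes of the pigment cells, had a median of -0.84 with 12 of 12 negative (preset adjusted p = 0.014, adjusted p = 0.73 with an estimated correlation). It was no longer called without cKO mouse 5 (adjusted p = 0.089) or with the muscle covariate (0.13), and its slide values were -0.91 blocked, -0.55 and -1.25. The list of SoxC genes and reported Sox4 targets had a median of -0.29, with Tead2 alone past the threshold over all genes and 2 of 7 adjusted over the list alone (preset adjusted p = 0.027, adjusted p = 0.54 with an estimated correlation). Its slide values were -0.35 blocked, -0.16 and -0.20. That call ended without WT mouse 6 (adjusted p = 0.1) or cKO mouse 4 (0.076). Another target of that list, Ezh2, was at -0.35 ± 0.092 (adjusted p = 0.16).

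Skeletal muscle genes had a median of 2.10 in cKO relative to WT, with 1 of 22 negative (Ttn 3.58 ± 1.4, adjusted p = 0.35; Myh1 3.41 ± 1.1, adjusted p = 0.28). Their mean level in single mice ranged from -4.05 (WT 3) to 3.89 (cKO 1). The list was called (preset adjusted p = 9.8e-10, adjusted p = 0.54 with an estimated correlation), and its slide values were 2.37 blocked, 3.56 and 1.29. Sebaceous gland genes were positive in 12 of 12 (median 0.29, preset adjusted p = 0.00016, 0.54 estimated; slide values 0.37 blocked, 0.33 and 0.56). The interferon response list had a median of 0.38 (0.00039 preset, 0.66 estimated; slide values 0.40, 0.47 and 0.30) and lost its call with the muscle covariate (adjusted p = 0.099). Interfollicular differentiation genes had a median of 0.11 (0.021 preset, 0.73 estimated; slide values 0.19, 0.0018 and 0.49), and basal keratinocyte genes a median of 0.17 (0.027 preset, 0.66 estimated; slide values 0.22, -0.04 and 0.39). The interfollicular call ended without WT 3 (0.052), WT 6 (0.086) or cKO 5 (0.87), and the basal call without WT 3 (0.052), WT 6 (0.061), cKO 4 (0.082) or cKO 5 (0.36) or with the muscle covariate (0.16). None of these lists had a member past the threshold over all genes or adjusted over the list alone.

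The genes that build the hair itself did not pass as groups with all mice, although several did without a single mouse. Hair shaft keratins had a median of -0.45 (adjusted p = 0.35; 12 of 14 negative), hair matrix regulators -0.35 (0.074; 15 of 16 negative; Shh -1.16 ± 0.48, adjusted p = 0.38) and inner root sheath genes -0.09 (0.54; 12 of 12 negative). For keratin-associated proteins the median was -0.12 and the mean -0.10 while the test direction was up (adjusted p = 0.91). The hair follicle stem cell and bulge list had a median of -0.01 (adjusted p = 0.95). Hair shaft values by slide were -0.51 blocked, -0.10 and -0.98, and those of the matrix list were -0.42, -0.19 and -0.64. Wnt targets had a median of -0.22 (0.093; Sp5 lower over all genes, Lgr5 -0.22) and hair cycle arrest signals -0.10 (0.54; Fgf5 -1.32 ± 0.44, adjusted p = 0.28). Among immune lists, the medians were -0.14 for lymphocytes (0.065; Cd3d -0.77 ± 0.18, Cd3g -0.90 ± 0.22 and Lck -0.43 lower adjusted over the list alone), -0.17 for Langerhans cells (0.12), -0.20 for macrophages (0.3) and 0.30 for mast cells (0.064; 1 higher adjusted over the list alone). The remaining medians were 0.09 for immediate early genes (0.14), -0.16 for cell cycle inhibitors (0.33), 0.02 for endothelium (0.43), 0.05 for nerve (0.43), -0.07 for fibroblasts (0.45), 0.12 for red cells (0.75) and -0.0041 for the companion layer (0.85; 1 lower adjusted over the list alone). For p53 targets the median was 0.01 and the mean -0.0097 (test up, 0.57), and for adipocytes they were -0.13 and -0.16 (test up, 0.96).

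Of the 20 lists not called for genotype, 11 were called without 1 mouse. Matrix regulators were called lower without cKO 2 (0.014) or cKO 6 (0.0014), with slide as a block (0.019) and without a filter (0.025). Hair shaft keratins (0.0062) and Wnt targets (0.012) were called lower without cKO 6, and Wnt targets also without a filter (0.035). Keratin-associated proteins were called lower without WT 2 (0.0077) or cKO 6 (0.0088) and higher without cKO 5 (0.00014). Lymphocyte genes were called lower without WT 4 (0.046), cKO 3 (0.017) or cKO 5 (0.00048), with slide as a block (0.047), without a filter (0.025) and with normexp and quantile normalization (0.023). Macrophage genes were called lower without WT 1 (0.019) and Langerhans cell genes without cKO 2 (0.026). Called higher were mast cell genes without WT 1 (0.0072), WT 5 (0.047) or cKO 4 (0.0089), adipocyte genes without cKO 5 (0.016), endothelial genes without WT 2 (0.048) and immediate early genes without cKO 4 (0.048). Without both WT mouse 5 and cKO mouse 5, fibroblast genes were called lower (0.026).

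**Figure D2:**
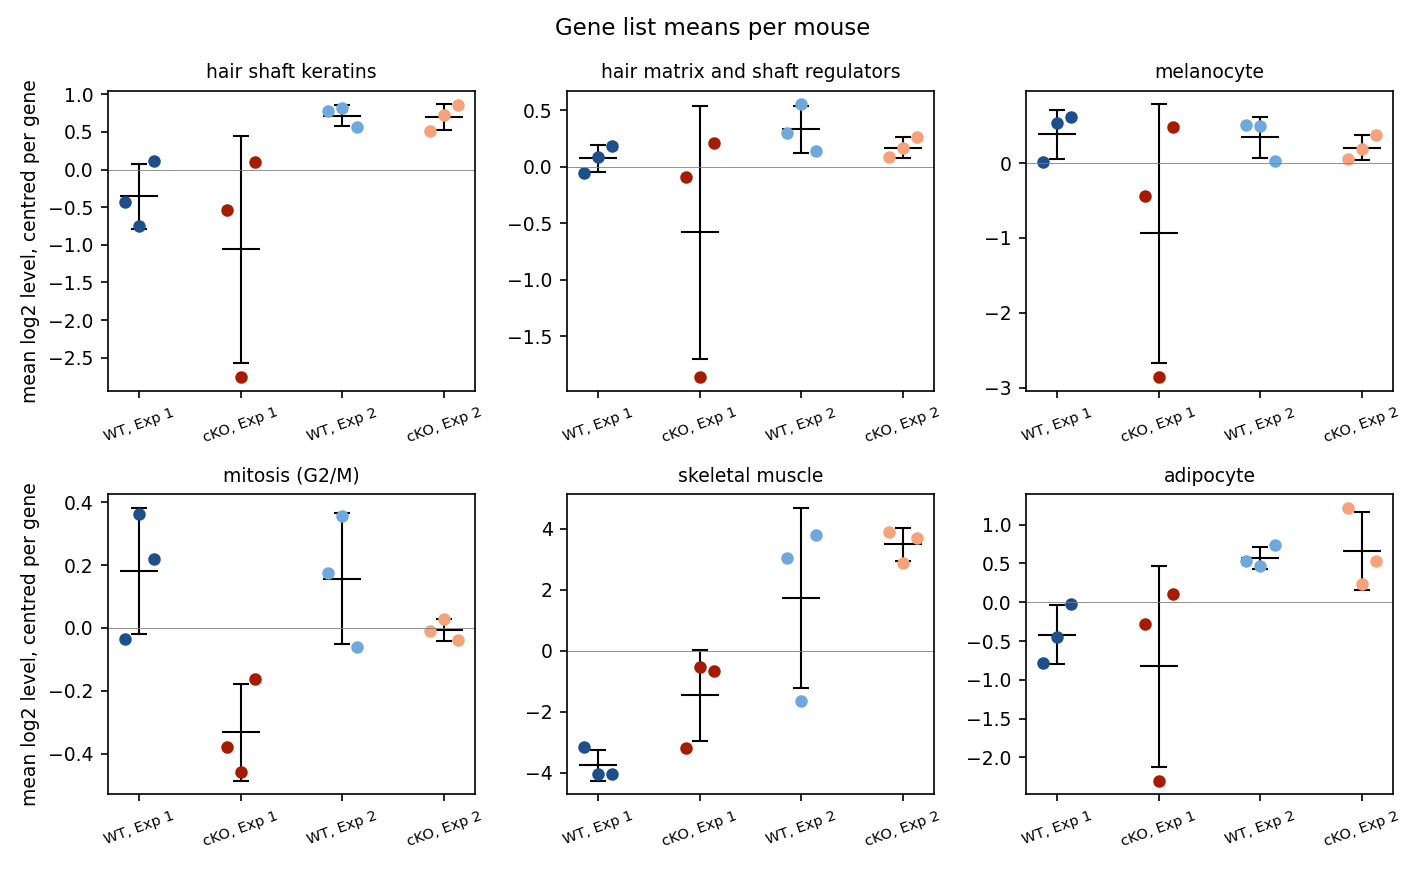
Mean log2 level of 6 gene lists (centred per gene) for each mouse (points) with group mean and SD, in WT and cKO skin of Exp 1 and Exp 2. cKO mouse 5 is the lowest mouse for hair shaft keratins (-2.76), hair matrix regulators (-1.86) and melanocyte genes (-2.86), and the skeletal muscle mean runs from -4.05 to 3.89.

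In Exp 1, where the mice were 68 to 72 weeks old, the genotype contrast asked which genes differ in older skin. Grp fell by 2.89 (SE 0.29, adjusted p = 0.0032; at least 3.96-fold), Mex3a by 2.86 (SE 0.15, adjusted p = 1.7e-05), Plppr3 by 2.81 (SE 0.24, adjusted p = 0.0012) and Dusp9, which encodes a MAP kinase phosphatase, by 2.19 (SE 0.33, adjusted p = 0.047). Refitted under the alternatives, Dusp9 kept its call in 3 of 29 fits and Mex3a in 28 of 30. Tead2 was lower by a log2 difference of -1.36 (SE 0.13, adjusted p = 0.0028). Eml5 (1.44 ± 0.18, adjusted p = 0.018, at least 2.0-fold) and Pcdh20 (1.15 ± 0.14, adjusted p = 0.018) were the 2 genes that rose. In total limma called 19 genes, 2 higher and 17 lower, with n = 3 and 3 mice and 1829 genes at an unadjusted p under 0.05. The count was 14 with slide as a block and 1 within slide 1. Within slide 2 it was 1318, where the contrast was cKO mouse 5 minus WT mouse 1 and all of the spread came from 1 pair of arrays, WT 4 and WT 6 (1 residual degree of freedom). In the fits by group within slide 1 it came from 2 pairs, WT 2 and 3 and cKO 2 and 6. Leaving out 1 mouse moved the count to 6 (WT 3), 8 (WT 2), 10 (WT 4), 11 (cKO 1), 12 (WT 5, WT 6 or cKO 4) or 56 (cKO 6). It was 7 with median scaling, 8 with the array-name tag, 8 in the authors' table (7 without its column of cKO mouse 1) and 7 with the muscle covariate.

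Mitosis genes in Exp 1 had a median of -0.57 (19 of 24 lower adjusted over the list alone, none over all genes; preset adjusted p = 5.1e-13, adjusted p = 0.55 with an estimated correlation). Replication genes had a median of -0.49 (2 adjusted over the list alone; 4e-09 preset, 0.55 estimated) and dermal papilla genes -0.56 (4 adjusted over the list alone; 0.00089 preset, 0.55 estimated). The slide values were -0.57 blocked, -0.59 and -0.46 for mitosis, -0.49, -0.37 and -0.45 for replication, and -0.56, -0.56 and -0.76 for dermal papilla. Melanocyte genes had a median of -1.49 (0.00037 preset, 0.56 estimated; -0.44 without cKO mouse 5; slide values -1.49, -0.61 and -3.15). Hair shaft keratins were at -0.79 (0.025 preset, 0.74 estimated) and matrix regulators at -0.55 (0.012 preset, 0.69 estimated). No member of these 3 lists passed over all genes or over the list alone. Hair shaft and matrix lists both turned to positive medians without cKO mouse 5 (0.04, adjusted p = 0.16, and 0.06, adjusted p = 0.74), and the hair shaft call also ended without WT 1 (0.1) or WT 3 (0.22). With the muscle covariate both calls ended (0.17 and 0.24). Their slide values were -0.79, 0.02 and -2.50 for hair shaft, and -0.55, 0.0024 and -1.73 for matrix.

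The other lists called in Exp 1 were higher for interfollicular differentiation (0.60, 4.5e-06 preset, 0.55 estimated; slide values 0.60, 0.27 and 1.17), skeletal muscle (2.32, 1.9e-05 preset, 0.56 estimated; 2.32, 2.03 and 2.95), sebaceous gland (0.49, 0.00045 preset, 0.55 estimated; 0.49, 0.22 and 0.94) and basal keratinocytes (0.38, 0.0018 preset, 0.55 estimated; 0.38, 0.20 and 0.73). They were also higher for interferon response (0.33, 0.022 preset, 0.69 estimated; 0.33, 0.23 and 0.28) and immediate early genes (0.25, 0.035 preset, 0.55 estimated; 0.25, -0.03 and 0.40). Lower lists were macrophages (-0.35, 0.0093 preset, 0.56 estimated; -0.35, -0.60 and 0.08), SoxC and targets (-0.41, 0.012 preset, 0.55 estimated; -0.41, -0.09 and -0.26), fibroblasts (-0.27, 0.028 preset, 0.56 estimated; -0.27, -0.42 and 0.21) and Wnt targets (-0.40, 0.035 preset, 0.55 estimated; -0.40, -0.27 and -0.66). The Wnt call ended with slide as a block (adjusted p = 0.057) and the interferon call with the muscle covariate (0.49). Leaving out cKO 5 ended the sebaceous (0.1), basal (0.13), immediate early (0.1) and Wnt (0.17) calls. Leaving out cKO 6 ended the macrophage (0.17), interferon (0.96) and fibroblast (0.25) calls, and leaving out cKO 2 those of fibroblasts (0.14), Wnt targets (0.059) and immediate early genes (0.073). Leaving out WT 1 ended the Wnt (0.1), interferon (0.16) and immediate early (0.14) calls, WT 2 the fibroblast call (0.067), and WT 3 the Wnt (0.071), fibroblast (0.13), macrophage (0.051) and immediate early (0.082) calls. Of the lists in this paragraph, members passed over the list alone only among SoxC and targets (2 of 7).

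Of the 14 lists not called in Exp 1, 8 were called without 1 mouse. Without cKO 5, adipocyte (0.0078), inner root sheath (0.013) and keratin-associated genes (0.00043) were called higher, and without cKO 6 the same lists were called lower (0.016, 0.037 and 2e-06). Keratin-associated genes were also called lower without WT 2 (3.1e-09). Lymphocyte (0.01) and companion layer genes (0.021) were called lower without cKO 5 and hair cycle arrest signals without cKO 2 (0.013). Endothelial genes were called higher without WT 2 (0.0056), and mast cell genes without WT 1 (0.0035), cKO 1 (0.037), cKO 4 (0.043) or cKO 5 (0.038). The 5 calls named for cKO 5 other than mast cells also appeared without both WT mouse 5 and cKO mouse 5 (at most 0.031).

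In Exp 2, where the mice were 16 to 20 weeks old, the same contrast asked which genes differ in younger skin. Mex3a fell by 2.39 (SE 0.15, adjusted p = 0.0001), Tes, which encodes a focal adhesion protein, by 1.83 (SE 0.21, adjusted p = 0.024), and Plppr3 by 1.78 (SE 0.24, adjusted p = 0.041; second probe opposite). Tead2 was lower by a log2 difference of -1.10 (SE 0.13, adjusted p = 0.024). Spink12 was at -3.49 ± 0.48 (adjusted p = 0.043), at least 2.67-fold lower, and Timd4, which encodes a phagocytic receptor of resident macrophages, was the 1 gene that rose (1.87 ± 0.24, adjusted p = 0.033, at least 3.22-fold). Refitted under the alternatives, Spink12 kept its call in 6 of 29 fits, Timd4 in 7 of 29 and Mex3a in 28 of 30. In total limma called 10 genes, 1 higher and 9 lower (n = 3 and 3; 755 at an unadjusted p under 0.05). The count was 6 with slide as a block, 79 within slide 1 (70 higher, 9 lower), where the contrast was cKO mouse 1 minus WT mouse 5, and 7 within slide 2, where it was cKO mouse 4 against WT mice 4 and 6. Only 2 and 1 of those genes were among the 10. Leaving out 1 mouse moved the count to 2 (WT 3, WT 4, WT 5 or cKO 1), 3 (cKO 3), 4 (cKO 4), 5 (WT 2 or cKO 6), 6 (WT 1) or 21 (cKO 5). Median scaling moved the median of all genes to -0.21 and gave 6 genes, the authors' table gave 3 (4 without its column of cKO mouse 1) and the muscle covariate 2. In Exp 2 the array-name tag coincided with genotype, so the 2 cannot be told apart within it, and with the tag as a term the count was 2.

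Langerhans cell genes, markers of the antigen-presenting cells of the epidermis, had a median of -0.37 in Exp 2 (preset adjusted p = 0.00075, adjusted p = 0.73 with an estimated correlation; slide values -0.44 blocked, -0.46 and -0.47), with Epcam (-0.58), H2-Eb1 (-0.44), H2-Aa (-0.40) and H2-Ab1 (-0.37) lower adjusted over the list alone. Their median was 0.25 in the authors' value table and stayed negative in that table without cKO mouse 1. Lymphocyte genes had a median of -0.39 (0.0014 preset, 0.74 estimated; slide values -0.36, -0.64 and -0.33). WT mouse 5 stood apart on this list (mean level 0.626, against 0.144 in WT 4 and 0.0989 in WT 6), and without it the median was -0.375 (adjusted p = 0.0028). With all mice, Cd3g (-1.39), Cd3d (-1.02) and Lck (-0.43) were lower adjusted over the list alone. The replication list was at -0.25 (0.0012 preset, 0.99 estimated; slide values -0.24, -0.47 and -0.03) and the mitosis list at -0.13 (adjusted p = 0.061). Mitosis genes were called lower without WT 1 (0.039), WT 6 (0.0027), cKO 3 (0.019) or cKO 6 (0.049), with slide as a block (0.00067) and without a filter (0.023). Adipocyte genes were called higher without cKO 3 (0.036), macrophage (0.02) and mast cell genes (0.013) higher without cKO 4, interfollicular genes lower without cKO 5 (0.01) and fibroblast genes higher with normexp and quantile normalization (0.006). Muscle genes were at 1.87 (3e-09 preset, 0.74 estimated; slide values 2.56, 6.43 and -0.36) and lost the call without WT mouse 5 (adjusted p = 0.69). Interferon genes were at 0.30 (0.00051 preset, 0.98 estimated; slide values 0.39, 0.49 and 0.35). Sebaceous genes were at 0.21 (0.016 preset, 0.99 estimated; slide values 0.24, 0.29 and 0.17), without a call when WT 6 (0.17) or cKO 1 (0.48) was left out. Keratin-associated proteins were at 0.05 (0.029 preset, 0.99 estimated), with slide values of 0.02, -0.05 and 0.25. The sign turned to -1.46 in the authors' table and to -0.09 with median scaling. Median scaling lowered the median of all genes in Exp 2, so that turn says nothing about this list relative to other genes. The keratin-associated call ended with slide as a block (0.22), without a filter (0.12), with the muscle covariate (0.1) and without WT 5 (0.35), cKO 3 (0.093) or cKO 4 (0.24). No member of the called replication, muscle, interferon, sebaceous and keratin-associated lists passed over all genes or over the list alone. Hair shaft keratins (-0.13, 0.45), matrix regulators (-0.16, 0.95), melanocyte genes (-0.11, 0.98) and dermal papilla genes (-0.16, 0.33) were not called. These values use the array of cKO mouse 1. The authors' column of that mouse differed from it by a median of -4.91 for hair shaft, -1.98 for matrix and -2.92 for melanocyte genes. For dermal papilla genes it differed by 0.012. Which of column and array belongs to the mouse is not settled, so the absence of a hair difference in Exp 2 was not shown.

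The interaction asked whether the genotype difference itself differed between experiments. Of the named coding genes none passed: the smallest p-values belonged to Timd4 (-1.78), Olfr173 (-4.06), Heg1 (-1.35), Tal2 (-2.44) and Gpr85 (-1.93) on the negative side and Pcdh20 (1.15), Trpc4 (1.65), Eml5 (1.29), Rpp25 (0.79) and Adra2c (1.18) on the positive side, each with an adjusted p of 1. Timd4, Olfr173, Heg1, Tal2, Gpr85 and Eml5 were each not above background in any mouse of at least 1 group, so their sizes are not reliable. The 1 gene called was 4930550L24Rik (interaction -4.23, adjusted p = 0.0099; named after its values were seen). It was above background in 3 of 3 WT mice of Exp 1 and in 0 of the other 9, so its difference in Exp 2 is background against background and the size is not reliable. In Exp 1 it was at least 5.83-fold lower in cKO. There were 511 genes at an unadjusted p under 0.05. The count was 0 with slide as a block (425 at an unadjusted p under 0.05), 7 within slide 1 and 392 within slide 2. It was 0 without WT 3, WT 4, cKO 3 or cKO 4 (367, 381, 411 and 441 at an unadjusted p under 0.05) and 2 without WT 1 or cKO 2. Across experiments, Mex3a, Plppr3, Sox4, Tead2 and Zfp422 were the 5 genes called in both with the same direction, where 0.00958 would be shared if the calls were independent. They are not fully independent, since both contrasts use the same estimate of each gene's spread, so 0.00958 makes the agreement look larger. Of the 19 genes called in Exp 1, 13 had the same direction at an unadjusted p under 0.05 in Exp 2, and 9 of the 10 called in Exp 2 had it in Exp 1 (r = 0.401 across all genes). Median scaling moved the median of all genes for the interaction to 0.14.

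**Figure D3:**
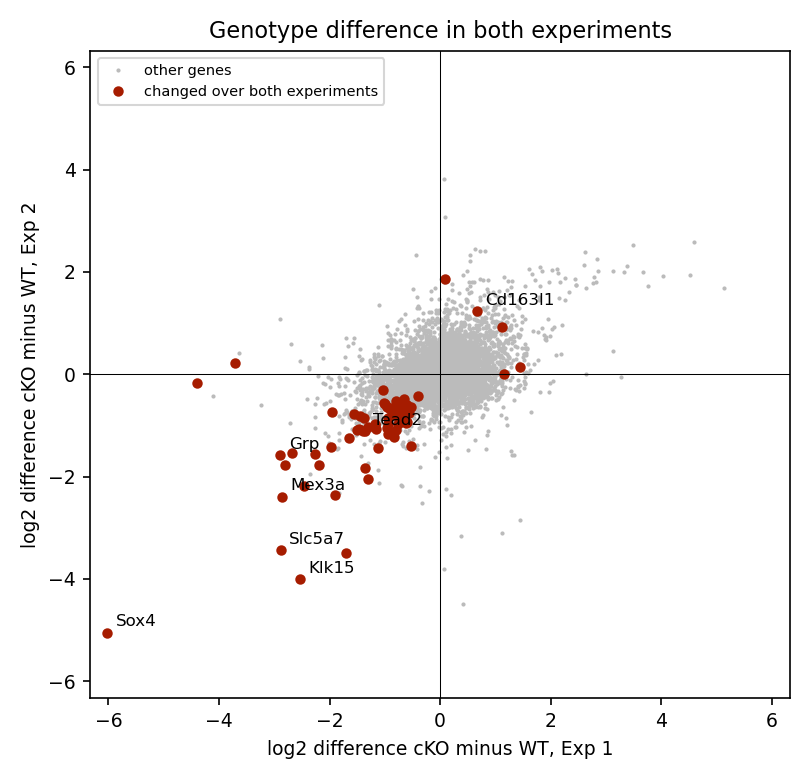
Log2 difference cKO minus WT in Exp 1 (x axis) against Exp 2 (y axis) for each of 16183 genes (grey points), with the 68 genes called over both experiments in red. Sox4 lies at -6.02 and -5.05 and Mex3a at -2.86 and -2.39.

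As groups, interfollicular differentiation genes differed by 0.93 between the experiments (preset adjusted p = 9.5e-08, adjusted p = 0.58 with an estimated correlation) and mitosis genes by -0.42 (2.4e-09 preset, 0.58 estimated). Melanocyte (-1.32, 0.00052 preset, 0.65 estimated), hair shaft (-0.72, 0.0027 preset, 0.69 estimated), matrix (-0.47, 0.017 preset, 0.74 estimated), keratin-associated (-0.39, 0.0016 preset, 0.78 estimated) and adipocyte genes (-0.46, 0.032 preset, 0.74 estimated) had more negative genotype differences in Exp 1. So had macrophage (-0.41, 0.00036 preset, 0.58 estimated), replication (-0.22, 0.00087 preset, 0.66 estimated), fibroblast (-0.27, 0.0016 preset, 0.58 estimated) and dermal papilla genes (-0.48, 0.012 preset, 0.58 estimated). Langerhans cell (0.52, 0.0016 preset, 0.58 estimated), basal (0.47, 0.0045 preset, 0.65 estimated) and lymphocyte genes (0.45, 0.032 preset, 0.65 estimated) had more positive ones. No member of these 14 lists passed over all genes or over the list alone. With cKO mouse 5 left out, the test turned direction for hair shaft (0.46), keratin-associated (0.18), matrix (0.17) and adipocyte genes (0.18), and the melanocyte (0.17), basal (0.18), dermal papilla (0.097), replication (0.13) and lymphocyte calls (0.26) ended. The matrix and adipocyte calls ended with the muscle covariate (0.053 and 0.053). The matrix call also ended with slide as a block (0.054) and without WT 6 (0.1), the keratin-associated call without WT 1 (0.084) or WT 3 (0.65), the dermal papilla call without WT 2 (0.059) and the fibroblast call without cKO 6 (0.051). The adipocyte call ended without WT 3 (0.26), WT 4 (0.05), WT 5 (0.13) or cKO 1 (0.43), and the lymphocyte call without WT 2 (0.059), WT 3 (0.062), WT 5 (0.087), WT 6 (0.053), cKO 1 (0.14) or cKO 4 (0.071).

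Of the 16 lists not called for the interaction, 9 were called without 1 mouse. Skeletal muscle genes were called higher without WT 5 (7.7e-11) and lower without WT 6 (0.049), and inner root sheath genes higher without cKO 5 (0.012) and lower without cKO 6 (0.038) or with normexp and quantile normalization (0.04). Immediate early genes were called higher without WT 2 (0.023) or cKO 3 (0.0016) and with slide as a block (0.001), sebaceous genes higher without WT 1 (0.036), cKO 1 (0.0089) or cKO 6 (0.013), mast cell genes higher without WT 1 (0.029) or cKO 1 (0.033), and endothelial genes higher without WT 2 (0.023). Hair cycle arrest signals were called lower without cKO 2 (0.0058), and interferon (0.011) and Wnt genes (0.022) lower without cKO 6. Without both WT mouse 5 and cKO mouse 5, muscle genes were called higher (8.1e-09) and the companion layer lower (0.03).

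Between slides the interaction medians kept their sign for interfollicular (0.78 blocked, 0.71 and 1.32), mitosis (-0.33, -0.20 and -0.45), melanocyte (-1.17, -0.21 and -3.30), basal (0.36, 0.31 and 0.53), dermal papilla (-0.44, -0.19 and -0.46), adipocyte (-0.64, -0.64 and -1.23), Langerhans (0.61, 0.56 and 0.40) and lymphocyte genes (0.45, 0.53 and 0.85). They changed sign between slides for hair shaft (-0.58 blocked, 0.31 and -2.53), keratin-associated (-0.34, 0.43 and -1.89), matrix (-0.37, 0.48 and -1.95), macrophage (-0.27, -0.60 and 0.27), replication (-0.19, 0.07 and -0.60) and fibroblast genes (-0.27, -0.65 and 0.21). In the authors' value table the medians of hair shaft (0.80), keratin-associated (1.11), matrix (0.21), replication (0.03), mitosis (0.03) and Langerhans genes (-0.18) had the opposite sign. None of these turned in that table without cKO mouse 1.

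Within WT skin, Exp 1 was compared with Exp 2 to describe how the older and younger mice differed. Sult1e1, which encodes a sulfotransferase that inactivates oestrogen, fell from -1.29 ± 0.73 in Exp 2 to -6.75 ± 0.11 in Exp 1 (SD, n = 3 and 3), at least 11.9-fold (difference -5.46, SE 0.42, adjusted p = 0.00088). Ptgis, the prostacyclin synthase gene, was lower by a log2 difference of -3.81 (SE 0.38, adjusted p = 0.0037), as were Inmt (-4.37 ± 0.82, adjusted p = 0.044) and the muscle gene Tcap (-8.07 ± 1.5, adjusted p = 0.045). Major urinary protein genes Mup17 (-3.93), Mup18 (-3.89), Mup19 (-3.82), Mup5 (-3.73), Mup20 (-3.67) and Mup4 (-3.55) were also lower, although their probes can read one another's transcripts. Ubd (3.33 ± 0.59, adjusted p = 0.039), Cd163l1 (1.68 ± 0.20, adjusted p = 0.011), Malat1 (1.61 ± 0.24, adjusted p = 0.029) and Serpina3j (1.64) were higher in Exp 1. Itgad, Olfr173, Ces1e, Dnah2 and B3gat2 were not above background in Exp 2 and were at least 8.18-fold, 4.41-fold, 4.36-fold, 2.99-fold and 1.94-fold higher in Exp 1. Sox4 differed by -0.22 (adjusted p = 0.53).

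In this contrast limma called 136 genes, 60 higher and 76 lower in Exp 1, with 2991 at an unadjusted p under 0.05. The count was 21 with slide as a block (8 higher, 13 lower), 5 within slide 1 (2 WT arrays of Exp 1 against 1 of Exp 2) and 702 within slide 2 (1 against 2). It was 0 with the muscle covariate (2055 at an unadjusted p under 0.05), 7 with the array-name tag, 4 in the authors' table (250 without its column of cKO mouse 1) and 272 with normexp and quantile normalization (150 higher, 122 lower). Median scaling moved the median of all genes to -0.15 and gave 277 genes, 32 higher and 245 lower. Leaving out 1 mouse moved the count to 6 (WT 2), 12 (WT 1), 14 (WT 3), 18 (WT 4), 42 (cKO 4), 77 (cKO 3), 414 (WT 5) or 597 (cKO 5).

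Keratin-associated protein genes, which encode the matrix of the hair fibre, had a negative difference in 50 of 50 in WT skin, with a median of -1.49 (0 lower over all genes, 35 adjusted over the list alone; preset adjusted p = 7.7e-18, adjusted p = 0.74 with an estimated correlation). Krtap19-1, at -2.55 (adjusted p = 0.075), was among them. Muscle genes were negative in 22 of 22 (median -5.98, 18 lower adjusted over the list alone; 1.4e-14 preset, 0.74 estimated), with Tnnt3 at -8.78 (adjusted p = 0.051). Hair shaft keratins had a negative sign in 14 of 14 (-1.11, 0.0008 preset, 0.81 estimated) and adipocyte genes in 15 of 16 (-0.93, 0.00092 preset, 0.81 estimated), with 0 members past the threshold over all genes or over the list alone in either. Macrophage genes had a median of -0.52, with C1qa at -1.27 (5 lower and 1 higher adjusted over the list alone; 0.00098 preset, 0.74 estimated). Higher lists were basal keratinocytes (0.45, 0.0015 preset, 0.74 estimated), sebaceous gland (0.51, 0.012 preset, 0.81 estimated) and companion layer (0.34, 0.049 preset, 0.80 estimated; Defb6 1.20 and S100a9 2.64 adjusted over the list alone), with 0 basal and 0 sebaceous members past either threshold. The sebaceous call ended without WT 1 (0.099) or without a filter (0.064). The companion call ended with slide as a block (0.05), without a filter (0.14), with the muscle covariate (0.15) and without WT 1 (0.089), WT 4 (0.055), WT 5 (0.065), WT 6 (0.065), cKO 2 (0.057), cKO 3 (0.053) or cKO 4 (0.055). The adipocyte call ended with the muscle covariate (0.055). Of the 22 lists without a call, 5 were called without 1 mouse: replication genes higher without WT 1 (0.028), and lower mast cell genes without WT 1 (0.012), endothelial genes without WT 2 (0.027), matrix genes without cKO 5 (0.036) and nerve genes without cKO 1 (0.04). Nerve genes were also called without a filter (0.021). With the muscle covariate matrix (0.038) and mitosis genes (0.04) were called lower and interferon genes higher (0.04). Slide values (blocked, slide 1, slide 2) were -1.59, -1.57 and -1.25 for keratin-associated proteins, -5.24, -1.98 and -7.44 for muscle, -1.35, -0.99 and -1.05 for hair shaft, and -1.31, -0.65 and -1.47 for adipocytes. They were -0.58, -0.38 and -1.02 for macrophages, 0.54, 0.36 and 0.65 for basal, 0.55, 0.20 and 0.66 for sebaceous and 0.47, 0.36 and 0.32 for companion genes.

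Within cKO skin the same contrast described how the older and younger mice differed. Cdkn2a, the gene of the cell cycle inhibitor p16, rose from -3.55 ± 0.18 in Exp 2 to 0.56 ± 0.52 in Exp 1 (SD, n = 3 and 3), a difference of 4.11 (SE 0.69, adjusted p = 0.015). In WT skin Cdkn2a differed by 1.57 (adjusted p = 0.26), and its interaction did not pass (2.55, adjusted p = 1). Defb4 (2.72 ± 0.39, adjusted p = 0.011, at least 5.09-fold), Il1f8 (2.33, 0.033), Cstdc6 (3.10, 0.049) and Flg2 (1.54, 0.025) were higher in Exp 1. Pcp4 (2.21 ± 0.27, adjusted p = 0.0087), Olah (2.81 ± 0.42, adjusted p = 0.011), Rgn (2.93, 0.017), Hoxb9 (2.67, 0.023), Shisal1 (at least 3.31-fold, 0.031) and Ptpn5 (at least 2.46-fold, 0.017) were also higher. The 10 largest decreases were all muscle genes or genes active in muscle: Myh4 (-7.39 ± 1.9, adjusted p = 0.041), Actc1 (at least 39.1-fold, 0.027), Mybpc2 (-6.74, 0.046), Ckmt2 (-6.73, 0.034), Mstn (at least 45.9-fold, 0.043), Fitm1 (-6.57, 0.043), Actn3 (-6.47, 0.036), Myh8 (-6.37, 0.049), Apobec2 (at least 30.7-fold, 0.030) and Casq1 (-6.30, 0.040). With the muscle covariate Mybpc2 (0.61), Myh8 (0.63) and Casq1 (0.13) turned positive. The Sox4 signal was -1.19 (adjusted p = 0.011) with the used probe, and the second probe, not above background, had the opposite sign.

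Here limma called 1615 genes, 871 higher and 744 lower in Exp 1, with 4556 at an unadjusted p under 0.05. The count was 146 with slide as a block (55 higher, 91 lower), 112 within slide 1 (4 higher, 108 lower), where the contrast was cKO mice 2 and 6 against cKO mouse 1, and 2988 within slide 2 (1345 higher, 1643 lower), where it was cKO mouse 5 against cKO mouse 4. It was 0 with the muscle covariate (2607 at an unadjusted p under 0.05), 92 with the array-name tag, 62 in the authors' table (1057 without its column of cKO mouse 1) and 1031 with median scaling (406 of them higher). Leaving out 1 mouse moved the count to 157 (cKO 3), 196 (cKO 4), 591 (cKO 1), 623 (cKO 5), 886 (cKO 2), 1010 (WT 4) or 1070 (WT 3). Of the 136 genes called in WT, 126 had the same direction at an unadjusted p under 0.05 in cKO, and 116 were called in both with the same direction, where 6.72 would be shared if the calls were independent (r = 0.817 across all genes). The calls are not fully independent, since both contrasts use the same estimate of each gene's spread, so 6.72 makes the agreement look larger.

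**Figure D4:**
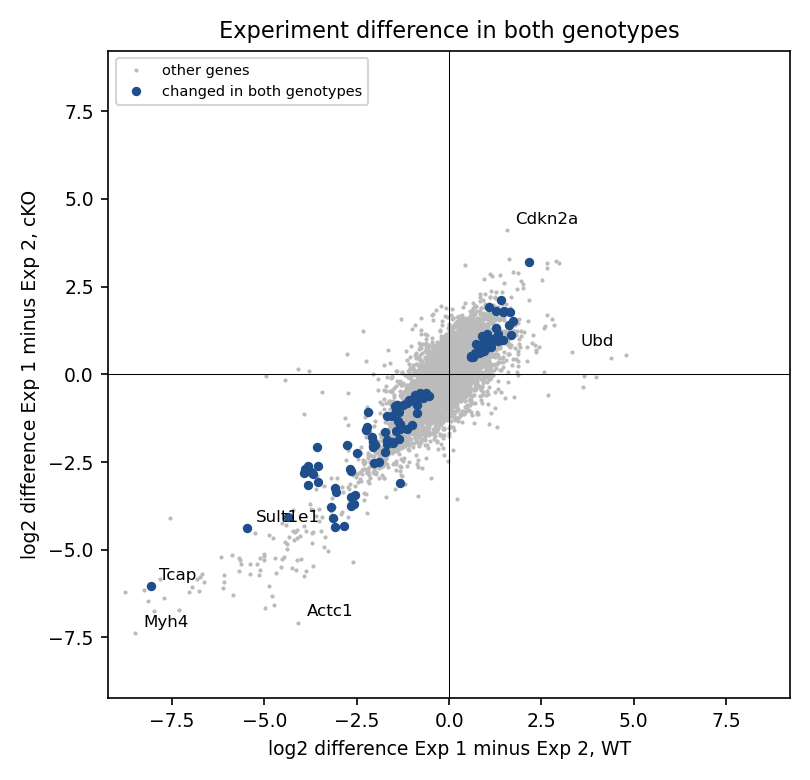
Log2 difference Exp 1 minus Exp 2 in WT (x axis) against cKO (y axis) for each of 16183 genes (grey points), with the 116 genes called in both genotypes with the same direction in blue. Across all genes r was 0.817.

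Keratin-associated protein genes had a median of -1.92 in Exp 1 relative to Exp 2 cKO skin, with 20 of 50 lower over all genes and 42 adjusted over the list alone (Krtap3-2 -2.61 ± 0.50, adjusted p = 0.019; Krtap19-1 -3.19 ± 0.62, adjusted p = 0.019; preset 4.8e-20, adjusted p = 0.53 with an estimated correlation). Hair shaft keratins had a median of -1.80 (Krt84 lower over all genes, -1.90; 13 adjusted over the list alone; 6.8e-07 preset, 0.53 estimated). Muscle genes had a median of -5.30 (16 of 22 lower, 19 adjusted over the list alone; 8.5e-12 preset, 0.53 estimated), macrophage genes -0.85 (8 of 12 lower, 10 adjusted over the list alone, with Cd163 at -2.88, C1qa at -1.48 and C1qc at -1.41; 6.2e-07 preset, 0.53 estimated) and adipocyte genes -1.65 (Thrsp -2.50 and Car3 -2.29 lower; 8.8e-06 preset, 0.53 estimated). Basal keratinocyte genes had a median of 0.87 (6 of 10 higher, 9 adjusted over the list alone, with Col17a1 at 1.43, Lamb3 at 1.29 and Krt14 at 1.15; 1.7e-05 preset, 0.53 estimated). Interfollicular genes had a median of 1.19 (8 of 19 higher; 15 higher and 2 lower adjusted over the list alone; 3.2e-05 preset, 0.53 estimated) and sebaceous genes 0.82 (Cidea 1.51, Krt79 1.11 and Scd3 1.04 higher, 6 adjusted over the list alone; 0.0017 preset, 0.53 estimated). Lower lists were mitosis (-0.36; Kif11 -0.74 and Tpx2 -0.65 lower; 4e-05 preset, 0.54 estimated), fibroblasts (-0.40; Pdgfra -0.86 and Col6a2 -0.69 lower, 6 adjusted over the list alone; 0.0054 preset, 0.53 estimated), matrix (-0.79; 0.0076 preset, 0.70 estimated) and melanocyte genes (-1.30; 0.013 preset, 0.70 estimated), the last 2 with 0 members past either threshold. Without cKO mouse 5 the matrix (0.47) and melanocyte (0.47) calls ended, and without cKO mouse 6 the fibroblast call (0.051). The fibroblast call also ended with the muscle covariate (0.35).

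Slide values for Exp 1 minus Exp 2 in cKO (blocked, slide 1, slide 2) were -1.93, -0.98 and -3.35 for keratin-associated proteins, -1.87, -0.79 and -3.82 for hair shaft, -5.33, -6.41 and -4.43 for muscle, -0.86, -1.05 and -0.61 for macrophages and -2.0, -1.30 and -3.41 for adipocytes. They were 0.84, 0.62 and 1.24 for basal, 1.12, 0.69 and 1.78 for interfollicular, 0.77, 0.15 and 1.17 for sebaceous, -0.39, -0.26 and -0.59 for mitosis, -0.34, -0.47 and -0.12 for fibroblasts, -0.89, -0.06 and -2.18 for matrix and -1.46, -0.05 and -3.67 for melanocyte genes. In the authors' table the matrix (0.15) and mitosis (0.13) medians had the opposite sign, and they did not turn in that table without cKO mouse 1. Of the 18 lists without a call, the bulge list was called higher without cKO 5 (0.024), the companion layer higher without cKO 6 (0.032), and dermal papilla genes lower without WT 1 (0.045) or cKO 6 (0.022), with slide as a block (0.04) and without a filter (0.012). Replication and inner root sheath genes were called lower without cKO 6 (0.022 each) and with the muscle covariate (0.008 and 0.046). Immediate early genes were called higher with slide as a block (0.036), and the bulge list also without both WT mouse 5 and cKO mouse 5 (0.034). Single genes of lists without a call also passed over all genes: Nog (-2.28) and Fgf10 (-1.53) were lower in dermal papilla, and Krt15 (0.85) and Sox9 (0.43) were higher in the bulge list. The T-cell genes Cd3g (1.64), Cd5 (1.40) and Cd3d (0.95), the Langerhans cell genes Cd207 (0.92) and Epcam (0.74), the companion layer genes Defb6 (1.45), Krt6b (1.41) and Krt6a (0.91) and the Wnt target Sp5 (1.52) were higher.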

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

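The tests of the value table column, of cKO mouse 5 as a mislabelled, follicle-poor or dim sample, and of follicle tissue and linked variants among the genes lower in cKO were chosen only after the result was seen.

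The skin of cKO mouse 5 (Exp 1) lay far below the other 5 cKO mice in its mean level of inner root sheath (-1.09), hair matrix (-1.86), hair cycle arrest (-0.591) and melanocyte genes (-2.86). WT mouse 5 lay above the other WT mice for lymphocyte genes (0.626). These were 5 of 64 measures compared, and chance alone sets about 1 in 20 groups apart in this way. A wrong label is argued against, since cKO mouse 5 was nearer the Exp 1 mean in 89.7% of 136 genes that differ between experiments in WT, and its Sox4 level was -3.88. Its array was the dimmest of the 12, with a 75th percentile of 364 and 53.9% of probes above background. Dimness as the whole cause is argued against, since genes of the 3 follicle lists that had not set the mouse apart had a median deviation of -2.43 (SD 0.78) among the brightest 5394 genes, which as a whole lay at 0.0246 with a 5th percentile of -1.3. The same genes lay at 0.0784 in cKO mouse 6, whose array was the next dimmest (396), and at -1.6 in WT mouse 2 (398). Those 3 lists were not chosen free of the pattern, since some came near to setting cKO mouse 5 apart. Its gap to the next cKO mouse, as a share of their range, was 0.616 for hair shaft, 0.565 for dermal papilla and 0.424 for keratin-associated genes, against a limit of 0.625. Earlier forms of that test were replaced: dim against bright genes gave 0.00582 within the -0.199 to 0.223 of the other arrays and decided nothing, and all follicle genes, which include lists that set the mouse apart, gave -2.23. Whether the sampled skin held fewer growing follicles stays open. The 3 follicle lists that had not set the mouse apart (3 of 3) were lowest in it of the 12 mice. The adipocyte list (-2.30), whose genes are not follicle genes, was lowest in it too. Whether that list follows follicle growth was not tested, so it does not decide the question. The Wnt, arrest, replication, mitosis and SoxC lists were lowest in it as well and do not decide it, since growing follicles also carry such genes. Genotype alone is argued against, since the other 5 cKO mice share it. Age alone is argued against, since WT 1, WT 2 and cKO 2 were also 72 weeks old. Their hair matrix means were -0.0505, 0.0908 and -0.0872, and their melanocyte means 0.0126, 0.536 and -0.436. Their inner root sheath and hair cycle arrest means also lay above those of cKO mouse 5. The place of sampling stays open too.

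In the authors' value table the column of cKO mouse 1 (Exp 2) differed from the array of that mouse with an SD of 0.692. Relative to the array, it was lower for hair shaft keratins (-4.91), keratin-associated proteins (-4.91) and inner root sheath genes (-3.72) and higher for Langerhans cell (1.49) and macrophage genes (1.2). The authors' normalization is argued against, since the highest SD among the other 11 columns was 0.0224. Another of the 12 arrays in its place is argued against, since the highest correlation of its deviations with any other array was 0.302, while the other 11 columns reached at least 0.997 with their own. Its correlation with its own array was 0.339, higher than with any other, so values of that array altered in another way stay open. Its Sox4 value was 6.81, within the 6.51 to 7.07 of the other cKO columns and below the 10.78 to 11.09 of the WT columns, so another Sox4 cKO sample remains a candidate explanation. Which of the column and the array belongs to the mouse cannot be settled from the values, and no biological explanation was tested.

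Of the 68 genes called for genotype, 63 were lower in cKO. Less growing follicle tissue as the whole cause stays open. In Exp 2 the hair matrix list had a median of -0.155 (SD 0.23) and the genes called lower a median of -0.972 (SD 0.91). The called genes were chosen for a decrease on these same arrays, which inflates their median, so the comparison cannot decide it. In Exp 1 with all mice the medians were -0.554 (SD 0.53) and -1.03 (SD 1), and without cKO mouse 5 they were 0.0552 (SD 0.31) and -0.972 (SD 1). The same limit holds there. The matrix median itself was smaller than the SD of its members in Exp 2 and in Exp 1 without cKO mouse 5. In Exp 2 it also rests on the array of cKO mouse 1, which differs from the authors' column of that mouse. Variants linked to the targeted allele are argued against as the whole cause, since 5 of the 68, Sox4 included, lie on the chromosome of Sox4, which holds 3.66% of the genes tested. Whether the 4 others there are linked to the allele was not tested. The decreases did not need cKO mouse 5, since 63 of the 63 were still lower at an unadjusted p under 0.05 without WT mouse 5 and cKO mouse 5. The genes were chosen at a stricter threshold on arrays that include those kept here, which favours this outcome. It is therefore a weak test of cKO mouse 5 as the cause. Loss of Sox4 in skin remains open and may lie behind these decreases. Tissue differences, follicle content among them, remain open too.

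The interaction of 4930550L24Rik was -4.23, a size that is not reliable, since the gene was above background in the 3 WT mice of Exp 1 and in 0 of the other 9 mice. As groups of genes, the genotype difference differed between experiments, at the preset correlation, for mitosis (adjusted p = 2.4e-09), interfollicular differentiation (9.5e-08), macrophage (0.00036), melanocyte (0.00052), replication (0.00087), keratin-associated (0.0016), fibroblast (0.0016), Langerhans cell (0.0016), hair shaft (0.0027), basal keratinocyte (0.0045), dermal papilla (0.012), hair matrix (0.017), adipocyte (0.032) and lymphocyte genes (0.032). None of the 14 held with an estimated correlation (smallest adjusted p = 0.58).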

How the results depend on the processing

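The skeletal muscle covariate, the fits without WT mouse 5 and cKO mouse 5, the authors' table without cKO mouse 1, the fits by group within slides and the exact test of list means were chosen only after the data were seen. Sox4 was lower in cKO at every setting, by log2 values from -4.12 to -5.92 apart from the second probe, which was at background in cKO (at least 23.2-fold lower). It passed the threshold at all but one: within slide 2 it was -5.32 (adjusted p = 0.184). Counts stayed within 1.5 times of the reported one at 13 of 33 settings for genotype (68 genes), 11 of 31 in Exp 1 (19), 9 of 31 in Exp 2 (10), 15 of 30 for the interaction (1), 8 of 31 for Exp 1 against Exp 2 in WT (136) and 13 of 31 in cKO (1615). Of 502 refits of the named genotype genes, 285 kept direction and call, 217 kept direction only and 0 reversed. For the contrast between experiments in cKO, 1252 of 2142 kept both and 3 reversed. Dim probes limit the smallest levels, since 9 of the 68 genotype genes were not above background in one genotype. Except where fewer mice, fewer genes or the term itself account for it, the cause was not tested.

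Scaling and values: normexp with quantile normalization gave 272 genes for WT between experiments. Median scaling gave 7 in Exp 1, 6 in Exp 2, 277 for WT and 1031 for cKO between experiments. The authors' value table gave 16 for genotype, 8 in Exp 1, 3 in Exp 2, 0 for the interaction (197 at an unadjusted p under 0.05), 4 for WT and 62 for cKO. Without its column of cKO mouse 1 it gave 36, 7, 4, 0, 250 and 1057.

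Filters, probes and variance: with no filter the counts were 45 for genotype, 11 in Exp 1, 3 in Exp 2 and 44 for WT between experiments. With probes above background on all 12 arrays they were 12 in Exp 1 and 0 for the interaction (447 at an unadjusted p under 0.05). Testing every kept probe, with or without a symbol (35375 probes), gave 5 probes in Exp 2 and 962 for WT. Trend with robust variance gave 0 for the interaction (502). Array weights gave 312 for genotype, 99 in Exp 1, 33 in Exp 2, 2 for the interaction and 1992 for WT.

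Batches and covariates: slide as a block gave 6 in Exp 2, 0 for the interaction (425 at an unadjusted p under 0.05), 21 for WT and 146 for cKO. The array-name tag gave 31 for genotype, 8 in Exp 1, 2 in Exp 2, 7 for WT and 92 for cKO. With mouse number as a replicate block the counts were 4 for genotype, 2 in Exp 1, 1 in Exp 2, 0 for the interaction (560), 0 for WT (2047) and 0 for cKO (1720). Equal mouse numbers did not mark pairs, since the deviations of mice 1 to 6 from their groups correlated at -0.26, -0.19, -0.16, -0.013, -0.10 and 0.072 across genes. Without an experiment term 38 genes were called for genotype, and with muscle and adipocyte means as covariates 35.

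Fits on fewer arrays: the 6 arrays of a contrast alone gave 3 in Exp 1, 4 in Exp 2, 37 for WT and 470 for cKO. Within slide 1 the counts were 5 for genotype, 1 in Exp 1, 79 in Exp 2, 7 for the interaction, 5 for WT and 112 for cKO. Within slide 2 they were 0 for genotype (997 at an unadjusted p under 0.05), 1318 in Exp 1, 392 for the interaction, 702 for WT and 2988 for cKO. In the fits by group the spread came from 2 pairs of arrays within slide 1 and from WT 4 and 6 alone within slide 2 (1 residual degree of freedom), so these counts are not reliable. Without WT mouse 5 and cKO mouse 5 the counts were 665 for WT and 958 for cKO.

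Skeletal muscle covariate: the counts were 11 for genotype, 7 in Exp 1, 2 in Exp 2, 0 for WT between experiments (2055 at an unadjusted p under 0.05) and 0 for cKO (2607). Mybpc2 (0.609), Myh8 (0.629) and Casq1 (0.129) reversed in cKO between experiments. The muscle list itself, which the covariate removes by construction, turned for genotype (adjusted p = 0.89), in Exp 1 (0.9), in Exp 2 (0.89), in WT (0.66) and in cKO (0.71).

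Leaving out each mouse gave 31 to 122 genes for genotype, 6 to 56 in Exp 1, 2 to 21 in Exp 2, 0 to 2 for the interaction, 6 to 597 for WT between experiments and 157 to 2324 for cKO. The lowest came without WT 3 for genotype and Exp 1, WT 2 for WT and cKO 3 for cKO. The highest came without cKO 6 for genotype, Exp 1 and cKO, and without cKO 5 for Exp 2 and WT.

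Gene lists: of 10 called for genotype, 0 were called with an estimated correlation, 0 by the exact permutation of list means per mouse, 6 with the muscle covariate, 10 with slide as a block and 7 to 10 with 1 mouse left out. The exact permutation could not have called a single list by itself, since its smallest p before adjustment is 0.005. Counted over all 30 lists, with lists newly called, slide as a block gave 12 and leaving out 1 mouse 7 to 14. In the other 5 contrasts 0 were called with an estimated correlation. Of lists not called with all mice, 11 of 20 for genotype, 8 of 14 in Exp 1, 5 of 23 in Exp 2, 9 of 16 for the interaction, 5 of 22 for WT and 5 of 18 for cKO were called without 1 mouse, among them matrix genes for genotype (adjusted p = 0.0014 without cKO 6). Lists that turned direction with 1 mouse or a pair of mice left out were the following. In Exp 1 without cKO mouse 5, hair shaft (adjusted p = 0.16) and matrix genes (0.74) turned direction. So did hair shaft (0.46), keratin-associated (0.18), matrix (0.17) and adipocyte genes (0.18) for the interaction. With each mouse left out, their adjusted p ranged from 6.1e-05 (without cKO 6) to 0.22 (without WT 3) for hair shaft and from 9e-05 (without cKO 6) to 0.74 for matrix genes in Exp 1. For the interaction it ranged from 5.4e-06 to 0.46 for hair shaft, from 8.9e-14 (without WT 2) to 0.65 (without WT 3) for keratin-associated, from 0.0002 to 0.17 for matrix and from 0.00098 to 0.43 (without cKO 1) for adipocyte genes. Without both WT mouse 5 and cKO mouse 5 the values were 0.17 and 0.71 in Exp 1, and 0.59, 0.03, 0.67 and 0.03 for the interaction, where the keratin-associated and adipocyte lists were thus called the other way.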

Other observations

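The set of WT mice of Exp 1 and the gap of 2 used for genes high in them alone were chosen only after the result was seen.

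In Exp 2 the T-cell receptor genes Cd3g and Cd3d were lowest in cKO skin. Cd3g was -0.50 in WT and -0.91 in cKO of Exp 1, and -1.16 and -2.55 in Exp 2, while Cd3d was -0.89 and -1.41, and -1.34 and -2.36 (group means, n = 3 each). The antigen presentation genes H2-Aa, H2-Ab1 and H2-Eb1 were 3.12, 6.71 and 6.42 in WT of Exp 2 and 2.73, 6.34 and 5.98 in cKO. The Wnt target Sp5 was lowest in the same group, at -3.02 against -1.62 in WT of Exp 2, and -1.51 against -0.99 in Exp 1. None of these genes passed the threshold for the interaction (adjusted p = 1), so a genotype difference confined to the younger mice was not shown.

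A small set of 3 genes was above background only in the WT mice of Exp 1, by more than 2 on the log2 scale over the other 9 arrays. These were 4930550L24Rik (-2.30, -2.42 and -1.95 in WT mice 1 to 3, at most -6.25 in the others), Gm773 (-3.77, -1.86 and -2.66, at most -6.12) and Itgad (-2.49, -2.24 and -0.80, at most -4.59). 4930550L24Rik and Gm773 lie on chromosome X and Itgad on chromosome 7. Of the 220 sets of 3 arrays, 1 had as many such genes, the WT mice of Exp 1 themselves, and the highest other set had 1. As the set and the gap were chosen after the genes were seen, this count does not bear on chance, and no explanation was tested.

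Other divisions of the same mice into groups were tried for each count of genes. For genotype, 100 of the 200 possible divisions were tried. Only the real one gave as many genes, with 68 against at most 2 in the others. A share of 1 in 100 is the smallest that this number of divisions can give, so chance is unlikely but not excluded. For the interaction, 25 of 100 divisions gave at least the real count of 1. Many of them kept WT mice 1, 2 and 3 together, as the real one does. The called gene was above background only in those mice, so such divisions could return it again. The share therefore does not measure chance, which is not excluded. The highest count of these divisions, 68, came from one that exchanges the genotypes in one experiment and so measures the genotype difference. For the contrasts of 3 against 3 mice there are 10 divisions, too few for a share under 0.05, and the real one alone gave as many in each (1 of 10). The real and highest other counts were 19 and 4 in Exp 1, 10 and 0 in Exp 2, 136 and 11 for WT between experiments, and 1615 and 1 for cKO. The 11 came from the division of WT mice 1, 4 and 6 from the rest, which follows slide 2, and with slide as a block the WT count was 21. The real division in Exp 2 follows the array-name tag, so tag and genotype cannot be told apart within it. With the tag as a term its count was 2. In Exp 1 the tag leaned the other way (P1 in WT 1, WT 2 and cKO 2, P2 in WT 3, cKO 5 and cKO 6). If the tag means the same in both experiments, its effect would turn sign there. Of the 10 genes called in Exp 2, 9 had the same direction at an unadjusted p under 0.05 in Exp 1, which argues against the tag alone for those 9.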
